A study of Mus musculus with 18 samples.

How the data were processed

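RNA was measured in macrophages sorted from wild-type (WT) mice and from mice lacking both Bhlhe40 and Bhlhe41 (DKO) on a C57BL/6 background. Per the labels, the cells came from 3 sources: alveolar macrophages of lungs at steady state, alveolar macrophages of mixed bone marrow chimeras, and peritoneal macrophages. The 6 groups hold 2 libraries each, described in the series design as biological replicates. The p-values below measure the spread between such replicates, pooled over the 6 groups. A gene with almost no reads in a population adds hardly any spread from it, so its SE in another population may be too small. Per the labels' protocols, alveolar macrophages were sorted as CD11c+ SiglecF+ CD11b low cells. In chimeras the WT cells were CD45.1+ CD45.2− and the DKO cells CD45.1− CD45.2+. Peritoneal macrophages were sorted as CD11b+ F4/80+ Tim4+ cells with intermediate MHC class II. Polyadenylated RNA was purified with magnetic beads and libraries were made with the NEBNext Ultra II kit.

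The submitters' processing notes name Bowtie 1.0.0, Bowtie2, TopHat 1.4.1, HTSeq 0.5.3 and DESeq2 1.2.10 and the builds mm9 and GRCm38.p3, without saying which step used which. The authors deposited TPM, a transcript abundance corrected for length and scaled to the same sum in every library, and it was read here from 1 table per population. Beside the TPM, the authors deposited for each population a log2 fold change of DKO over WT, a p-value and an adjusted p-value, and a signal column holding the mean of normalized counts. That column has the name that the tool of the authors, DESeq2, gives to counts divided by size factors and averaged over the libraries of a comparison. Some feature names end in suffixes whose meaning is not given in the files, such as IMP_OVL on the Bhlhe40 feature. Symbols were taken from the names with the suffix removed, and the 474 features marked IMP_DUP were matched to no gene list. No coordinates were used, except that which genes neighbour each other was read from a RefSeq table of the assembly GRCm38.p6, in which 11535 of the features tested have a position. Below, near a gene means among the 50 such features on either side of it, and not adjacent to it. Pparg, for instance, lies 32 and Plxnd1 40 features from Bhlhe40. The 6 ChIP-seq samples were not analysed here.

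TPM is not a count and keeps no depth of its own. The deposited mean normalized counts, combined with the TPM of features read in 1 library of a comparison, gave the value of a single read in each library. All values (100.0% in every library) then came out within 0.01 of a whole number of reads. The recovered depth was 6.59 M (1e6) reads in DKO chimera replicate 1 and between 16.51 and 29.34 M in the other libraries. Counting intervals and floors given below come from these reads, hold at the 95% level and cover counting error only. Where a group holds 0 reads, a bound was computed against 3 reads over the group. Where it holds 1 to 3, the ratio of read shares is given with its exact conditional binomial interval.

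Values were tested as log2(TPM + 1) with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit and eBayes with an intensity trend), with the 6 group means as the only terms and all 12 libraries in the fit, leaving 6 residual degrees of freedom. Features with a TPM of at least 1 in at least 2 libraries entered, 12303 in all. Tests were two-sided, and p-values were adjusted by the Benjamini-Hochberg method over all features tested; adjusted p under 0.05 counts as passing. Fold changes are on the log2(TPM + 1) scale, which understates the change of low genes. Because a TPM column is a composition, splits of all genes and of the lists into higher and lower are also given after rescaling each library by its median of ratios. Rescaling moved the median log2 fold change of all features from -0.22 to 0.00 in steady-state alveolar macrophages, from -0.09 to 0.02 in peritoneal macrophages and from 0.01 to 0.00 in chimeras. Gene lists are described relative to the median of all features.

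Before the data were examined, 30 gene lists were fixed (macrophage markers by tissue, pathways, and markers of other cells that a sort could let through), and the 27 with at least 5 tested members were compared with the other genes by camera at a preset correlation of 0.01, adjusted over the lists of a comparison. Each list was also tested with the correlation estimated from the residuals and with fry. Of 13, 8 and 15 lists past the threshold in steady-state alveolar, chimera and peritoneal macrophages, the call held with an estimated correlation for 1, 0 and 0. The lists of T and NK cells, of eosinophils and mast cells, and of erythrocytes and platelets had too few tested members. A tissue signature was defined as genes past the threshold with a log2 difference of at least 2 between WT alveolar and WT peritoneal libraries, always from the WT alveolar group that was not in the DKO comparison tested. The 3 DKO comparisons share no library.

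The rule for naming genes was fixed with the lists. Bhlhe40 and Bhlhe41 come first. In each DKO comparison it takes the 12 highest and 12 lowest genes past the threshold that have a mean TPM of at least 5 in the higher group and no overlap between DKO and WT libraries, leaving out predicted genes, pseudogenes and microRNAs. In each interaction it takes the 5 highest and 5 lowest. From each list described it takes members past the threshold or with the smallest p. Genes named outside this rule are said to be so.

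The alternatives tried were pseudocounts of 0.1 and 5, no filter and a minimum of 5 TPM, median-of-ratios and quantile scaling, a fit on only the groups compared, no intensity trend, a robust variance, the replicate number as a block, each library left out in turn, a minimum of 2-fold, other sizes of the tissue difference, and the authors' own calls. A fit with voom weights on the recovered reads was added after the files were seen. The fit was tested on simulated libraries of the same depth in which 12718 features entered the fit and 67, 67 and 66 of them were changed by 1.5-fold, 2-fold and 4-fold in each comparison. At 1.5-fold, 37.3% passed in steady-state alveolar macrophages, 56.7% in chimeras and 43.3% in peritoneal macrophages. At 2-fold the shares were 88.1%, 80.6% and 88.1%, and at 4-fold 90.9%, 100% and 93.9%. Among simulated features that were not changed, 54, 33 and 16 passed, which is 27.3%, 17.3% and 9.6% of all simulated calls and above the 0.05 that the threshold sets. Of these 43, 19 and 12 had a mean TPM under 1 over the libraries of the other populations. The cause was not tested. The share of false calls depends on how many features truly change. Far fewer changed in the simulation than passed in the data, so these shares do not carry over to the counts below. Low-count intervals and the figures were made with Python 3.11.15, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9.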

Results

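Alveolar macrophages clear surfactant and debris from the air spaces of the lung, and peritoneal macrophages live free in the fluid of the abdominal cavity. Bhlhe40 and Bhlhe41 are related basic helix-loop-helix repressors of transcription. Polyadenylated RNA was sequenced from WT and DKO macrophages of 3 sources: alveolar macrophages of steady-state lungs, alveolar macrophages of mixed bone marrow chimeras, in which marrow of both genotypes rebuilds the blood cells of the same recipients, and peritoneal macrophages. Each of the 6 groups had 2 libraries. The recovered depth was 19.82 and 17.62 M (1e6) reads in WT and 18.15 and 19.41 M in DKO steady-state alveolar libraries. It was 16.51 and 20.36 M in WT and 6.59 and 20.08 M in DKO chimera libraries. Peritoneal libraries had 29.34 and 23.57 M reads in WT and 24.49 and 24.03 M in DKO. TPM values below are means ± SD of 2 libraries, changes are log2 fold changes of DKO over WT ± SE of the limma fit, and higher or lower means in DKO relative to WT.

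Bhlhe40 was expressed in every WT library and was lower in every DKO library. In steady-state alveolar macrophages its gene-level TPM was 526.7 and 558.9 in WT and 122.3 and 98.67 in DKO, a remaining level of 20.4%. In chimeras it was 940.3 and 663.6 in WT and 242.7 and 193.2 in DKO, or 27.2%. In peritoneal macrophages it was 213.5 and 246.6 in WT and 85.5 and 65.68 in DKO, or 32.9%. The changes were -2.29 ± 0.19, -1.86 ± 0.19 and -1.60 ± 0.19, with adjusted p = 1.23e-05, 9.39e-05 and 0.000475. Bhlhe41 did not fall in any population. Its TPM was 86.65 and 77.59 in WT and 155.8 and 155.4 in DKO steady-state libraries, and 100.3 and 88.62 in WT and 110.1 and 111.5 in DKO chimera libraries. In WT peritoneal libraries it was low, at 3.677 and 1.905, and in DKO peritoneal libraries it was 75.42 and 83.22. Its changes were 0.92 ± 0.18 in steady state, 0.23 ± 0.18 in chimeras and 4.44 ± 0.18 in the peritoneum, with adjusted p = 0.00212, 0.376 and 6.93e-07. A gene-level TPM takes in whatever is transcribed outside the deleted part, so neither the Bhlhe41 values nor the remaining Bhlhe40 signal check a genotype.

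**Figure D1:**
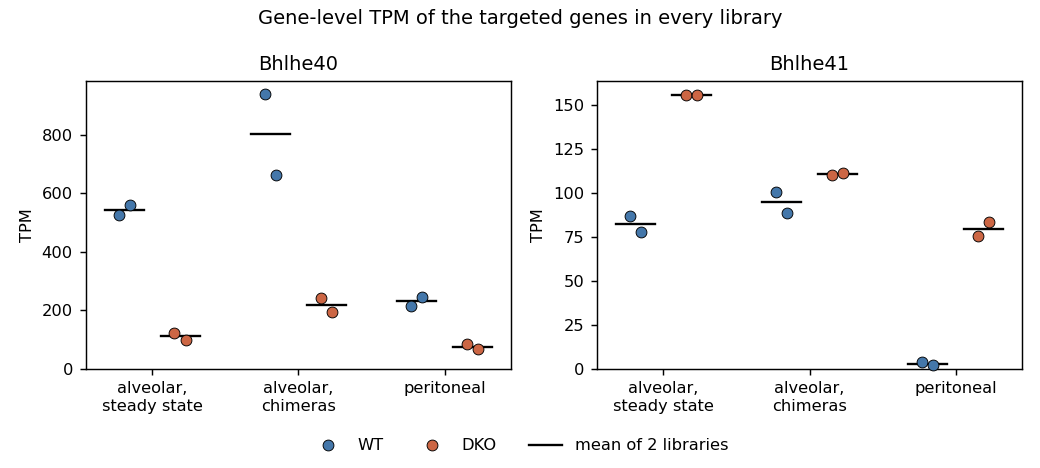
TPM of Bhlhe40 and Bhlhe41 in each of the 12 libraries, by population and genotype, with points for libraries and bars for their means. Bhlhe40 is lower in all DKO libraries than in the WT libraries of the same population, and Bhlhe41 goes from 2.79 TPM in WT to 79.3 TPM in DKO peritoneal macrophages.

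The difference between WT alveolar and WT peritoneal macrophages sets the tissue identities against which the DKO changes can be placed. Alveolar macrophages had Pparg, the transcription factor they need for surfactant handling, at 304 ± 7.42 TPM against 2.23 ± 0.612 in the peritoneum. They had Siglec5, an older symbol for the sorting marker Siglec-F, at 579 TPM and the chitinase-like Chil3 higher by 11.23 ± 0.26. Peritoneal macrophages had Gata6, the transcription factor of cavity macrophages, at 153 ± 16.3 TPM against 0.109 ± 0.154, and the lipoxygenase gene Alox15 at 8356 ± 112 TPM, listed at 0 in the alveolar libraries. They also had far more of the lipid carrier Apoe (-8.16 ± 0.15, alveolar over peritoneal) and the complement gene C1qb (-12.92 ± 0.18). Bhlhe40 was higher in alveolar cells by 1.24 ± 0.19 and Bhlhe41 by 4.49 ± 0.18. Of 26 alveolar macrophage markers, 23 were higher in alveolar cells and 2 in peritoneal cells, the fatty acid carrier Fabp4 (-2.84 ± 0.15) and the scavenger receptor Marco (-1.41 ± 0.22). Of 21 peritoneal markers, 20 were higher in peritoneal cells and 1 in alveolar cells. Adjusted over the list alone, the counts were 23 and 2, and 20 and 1, as they were after rescaling. In all, 8368 of 12303 genes passed, 5081 higher in alveolar and 3287 in peritoneal cells, or 4207 and 4256 after rescaling. Library numbers in the titles differ by population, so tissue and library series cannot be separated here.

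In steady-state lungs, the comparison of DKO with WT alveolar macrophages asks what these repressors do in a resident macrophage. DKO cells had more of transcripts that WT alveolar macrophages hardly had, or had at a much lower level, and that are abundant in most other resident macrophages. The C1q genes, which encode the recognition subunit of complement, went from 1 or 2 reads each over both WT libraries to 1077 ± 263 TPM for C1qb, 361 ± 104 for C1qc and 337 ± 113 for C1qa. Apoe, which carries cholesterol out of macrophages, was 6302 ± 215 TPM in DKO and 94.5 ± 0.377 in WT cells (6.04 ± 0.15, adjusted p = 4.04e-09). Epcam, an adhesion molecule of epithelium that WT alveolar macrophages also had, fell from 117 ± 6.42 to 0.953 ± 0.282 TPM (-5.93 ± 0.21, adjusted p = 3.73e-08).

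Beside the C1q genes and Apoe, the highest changes were in Pianp (7.67 ± 0.17), in Mfge8, a bridge between phagocytes and dying cells (6.68 ± 0.34), in Igf2r, the sorting receptor for lysosomal enzymes (6.30 ± 0.12), in Tmem37 (6.16 ± 0.19), in the protease gene Htra4 (6.14 ± 0.16), in the myelin protein gene Pmp22 (5.95 ± 0.16), in Gas7 (5.93 ± 0.20) and in the chemerin receptor gene Cmklr1 (5.69 ± 0.34). Mfge8 had 1176 and 3064 TPM in the DKO libraries and 19.55 and 15.66 in WT. For genes with few WT reads the ratio of read shares is the better guide: 18334 for C1qb (95% interval 3290 to 724189), 6112 for C1qc (1097 to 241449), 2936 for C1qa (812 to 24248), 368 for Tmem37 (144 to 1354) and 723 for Cmklr1 (282 to 2655). These intervals leave out the spread between libraries. With 1 library left out the ratio ran from 372 to 1531 for Cmklr1 and from 231 to 780 for Tmem37. For C1qb, C1qc and C1qa it went down to 8627, 2876 and 1554, or to at least 3236, 1079 and 921 where the WT library kept had 0 reads. The lowest changes were in Epcam, in the growth-response gene Egr3 (-5.86 ± 0.36), in Pmepa1, a TGF-beta target that dampens TGF-beta signalling (-5.43 ± 0.10), in the uridine kinase gene Uck2 (-5.13 ± 0.15), in the defensin-like Spag11b (-4.76 ± 0.21), in Egr1 (-4.21 ± 0.72), in the angiogenesis inhibitor Vash1 (-4.17 ± 0.12), in the growth factor Areg (-4.10 ± 0.40), in the nuclear receptor gene Nr4a3 (-3.86 ± 0.78), in the lipase inhibitor G0s2 (-3.78 ± 0.36) and in the small RNAs Scarna9 and Snord58b. Spag11b had 2 reads in DKO and 752 in WT, a ratio of 0.00265 (0.00032 to 0.00961). Nr4a3 was uneven between the DKO libraries, at 107.6 and 9.314 TPM against 435.6 and 538.3 in WT. Scarna9 had 13 and 8 reads in the WT libraries and 1 and 0 in DKO, and Snord58b had 0 in DKO, too few for a fold.

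Macrophages take on markers of the tissue they live in. Of 14 markers of Kupffer cells and splenic macrophages in DKO steady-state alveolar cells, there were 8 higher, 4 lower and 2 not passing, or 8 and 4 adjusted over the list alone and 8 and 3 after rescaling. Camera on Kupffer and splenic markers gave adjusted p = 0.000678, and adjusted p = 0.0676 with an estimated correlation. The higher ones included the adhesion molecule Vcam1 (5.02 ± 0.16), the lectin Fcna (5.01 ± 0.18) and Spic, the transcription factor of iron-recycling macrophages (2.77 ± 0.21). The lower ones included the inhibitor of DNA binding Id3 (-3.25 ± 0.25) and the platelet-type lectin Clec1b (-1.44 ± 0.26), which lies near Bhlhe41. Among 22 markers of interstitial macrophages and monocytes there were 9 higher, 2 lower and 11 not passing, or 9 and 2 adjusted over the list alone and 9 and 2 after rescaling, with Csf1r, the receptor for the macrophage growth factor, higher by 0.96 ± 0.08 and the CD11b gene Itgam by 2.41 ± 0.31. Camera on interstitial and monocyte markers gave adjusted p = 2.12e-06, and adjusted p = 0.0731 with an estimated correlation. This list holds C1qa, C1qb, C1qc and Apoe, already named above as higher. Among 21 peritoneal markers there were 7 higher, 0 lower and 14 not passing, or 7 and 0 adjusted over the list alone and 8 and 0 after rescaling. Camera on peritoneal markers gave adjusted p = 2.99e-05, and adjusted p = 0.196 with an estimated correlation. Cd93, a receptor of phagocytes, rose by 3.76 ± 0.20, Saa3, an acute-phase lipid carrier, had 523 reads in DKO and 0 in WT libraries (at least 174-fold higher), and Timd4, which encodes Tim4, had 38 and 0 (at least 12.6-fold). Saa3 was uneven between the DKO libraries, at 24.85 and 95.1 TPM, and with 1 library left out these bounds went down to 68.8-fold and 5.94-fold. Gata6 was not among the genes that passed. The 26 alveolar markers went both ways, with 7 higher, 13 lower and 6 not passing, or 7 and 14 adjusted over the list alone and 8 and 10 after rescaling. Camera on alveolar markers gave adjusted p = 0.9, and adjusted p = 0.937 with an estimated correlation. Siglec5 (-1.14 ± 0.13), the keratin Krt19 (-1.68 ± 0.10), the carbonic anhydrase Car4 (-1.06 ± 0.14) and Pparg (-0.76 ± 0.15), which lies near Bhlhe40, were lower. Marco (3.36 ± 0.22), Fabp4 (2.86 ± 0.15) and the CD11c gene Itgax (0.66 ± 0.09) were higher.

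Macrophages of the lung turn over large amounts of lipid and protein. Among 15 targets of the sterol receptor LXR and genes of cholesterol efflux there were 10 higher, 2 lower and 3 not passing, or 10 and 2 adjusted over the list alone and 12 and 1 after rescaling. Camera on LXR targets gave adjusted p = 4.71e-08, and adjusted p = 0.0212 with an estimated correlation. They included the apolipoprotein Apoc2 (3.62 ± 0.19), the efflux pump Abca1 (1.45 ± 0.14) and the LXR gene Nr1h3 (0.79 ± 0.14). Lysosomal and phagocytic genes rose as a set, with 16 higher, 1 lower and 10 not passing of 27, or 16 and 1 adjusted over the list alone and 22 and 0 after rescaling. Camera on lysosomal genes gave adjusted p = 6.93e-12, and adjusted p = 0.0676 with an estimated correlation. The scavenger receptor Msr1 rose by 3.38 ± 0.13, and the proteases Ctsl and Ctsb by 2.12 ± 0.12 and 1.78 ± 0.11. Of 28 interferon-response genes there were 16 higher, 2 lower and 10 not passing, or 16 and 2 adjusted over the list alone and 20 and 0 after rescaling. Camera on interferon-response genes gave adjusted p = 1.15e-08, and adjusted p = 0.135 with an estimated correlation. The GTPase Gbp3 (2.01 ± 0.14) and the interferon regulator Irf7 (1.41 ± 0.12) were among them. Chemokine genes went both ways, with 11 higher, 4 lower and 7 not passing of 22, or 11 and 4 adjusted over the list alone and 11 and 4 after rescaling. Camera on chemokine genes gave adjusted p = 0.000855, and adjusted p = 0.135 with an estimated correlation. Cxcl16 (3.89 ± 0.28) and Ccl9 (3.62 ± 0.35) were higher, and Cxcl14 (-2.55 ± 0.18), Ccl22 (-2.01 ± 0.14) and Ccl2 (-1.77 ± 0.36) were lower. Growth factor and cytokine receptors gave 8 higher, 3 lower and 11 not passing of 22, or 8 and 3 adjusted over the list alone and 12 and 3 after rescaling, with the G-CSF receptor gene Csf3r at 2.58 ± 0.19 and the VEGF receptor gene Flt1 at -1.79 ± 0.11. Camera on receptor genes gave adjusted p = 0.00517, and adjusted p = 0.498 with an estimated correlation. Matrix genes and proteases gave 6 higher, 2 lower and 9 not passing of 17, or 6 and 2 adjusted over the list alone and 6 and 1 after rescaling, with the metalloproteases Adam8 (4.88 ± 0.22) and Mmp12 (4.48 ± 0.29) higher. Camera on matrix genes gave adjusted p = 0.000637, and adjusted p = 0.249 with an estimated correlation.

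Genes of the cell cycle and of the early response to stimulation were lower. DNA replication and S phase genes gave 0 higher, 22 lower and 6 not passing of 28, or 0 and 25 adjusted over the list alone and 0 and 13 after rescaling, including Mcm7 (-0.81 ± 0.13) and Rrm1 (-0.92 ± 0.16). Camera on S phase genes gave adjusted p = 0.00168, and adjusted p = 0.674 with an estimated correlation. Genes of mitosis gave 0 higher, 27 lower and 1 not passing of 28, or 0 and 27 adjusted over the list alone and 0 and 24 after rescaling, including the cyclin Ccnb2 (-1.28 ± 0.19) and the kinase Aurka (-1.10 ± 0.17). Camera on genes of mitosis gave adjusted p = 0.000118, and adjusted p = 0.672 with an estimated correlation. The proliferation marker Mki67 (-1.26 ± 0.44) no longer passed after rescaling. Immediate-early and heat shock genes gave 1 higher, 17 lower and 6 not passing of 24, or 1 and 17 adjusted over the list alone and 1 and 13 after rescaling. Camera on immediate-early genes gave adjusted p = 0.0215, and adjusted p = 0.603 with an estimated correlation. Beside Egr1 and Egr3, Nr4a1 (-2.92 ± 0.61), Fosb (-2.44 ± 0.39) and the chaperone Hspa8 (-0.93 ± 0.10) fell, while Ier3 (2.12 ± 0.22) rose. The DKO libraries differed from each other in Egr1, at 55.27 and 25.8 TPM against 690.1 and 744.2 in WT, and in Nr4a3. Relative to counting noise the DKO steady-state replicates were the least alike of the 6 groups (chi-square per degree of freedom 31.51, against 5.47 to 12.72 in the others). Camera on this list gave adjusted p = 0.00313 without DKO replicate 1 and 0.00574 without DKO replicate 2. Of 5 markers of endothelium and fibroblasts there were 1 higher, 0 lower and 4 not passing, or 1 and 0 adjusted over the list alone and 2 and 0 after rescaling, the higher one being Pdgfra, a receptor of fibroblasts, at 16.6 ± 1.21 TPM in DKO and 0.0672 ± 0.00731 in WT. Camera on endothelial and fibroblast markers gave adjusted p = 0.0121, and adjusted p = 0.34 with an estimated correlation.

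The remaining lists did not pass in steady state. With counts after rescaling in brackets where they differ, the numbers of higher and lower genes were 3 and 5 (4 and 3) for microglia (of 14), 5 and 12 (7 and 9) for macrophage transcription factors (of 26), 2 and 11 (5 and 5) for inhibitors of the cell cycle (of 17), 1 and 8 (2 and 4) for cholesterol synthesis (of 22), 4 and 13 (6 and 8) for fatty acid handling (of 27) and 5 and 7 (5 and 6) for inflammatory cytokines (of 20). They were 1 and 3 (1 and 2) for MHC class II (of 11), 1 and 7 (1 and 3) for the circadian clock (of 18), 4 and 8 (7 and 3) for hypoxia and glycolysis (of 21), 2 and 2 (3 and 2) for lung epithelium (of 9), 1 and 1 (1 and 0) for B cells, 2 and 1 for neutrophils (of 5 each) and 1 and 4 (1 and 3) for dendritic cells (of 10). The smallest adjusted p was 0.114 and the largest 0.9, that of the alveolar markers. For alveolar markers and inflammatory cytokines the median lay below that of all genes and the mean above it. For transcription factors, lung epithelium, B cells and dendritic cells the median lay above and the mean below, with camera pointing up. Of the lists too small to test, the T cell adapter Lat was 1.28 TPM in DKO and 3.35 in WT, and the platelet chemokine Pf4 was 77.3 and 5.51. Pf4 was uneven, at 35 and 120 TPM in the DKO libraries. WT peritoneal macrophages had it at 6874 TPM, and the platelet genes Ppbp, Gp9 and Itga2b were at most 1.68 TPM in any library. Pf4 alone therefore does not point to platelets. In all, 6337 of 12303 genes passed in steady state, 1495 higher and 4842 lower, or 2513 and 2206 of 4719 after rescaling. Changes of at least 2-fold numbered 538 higher and 663 lower, or 704 and 377 after rescaling.

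In the chimeras, WT and DKO alveolar macrophages grew in the same recipients, so the comparison asks which changes belong to the cells and not to the lung around them. The C1q genes, Apoe, Pianp, Gas7 and Igf2r were again among the 12 highest genes, while of the 12 lowest in steady state only Epcam was again among the 12 lowest. C1qb was 587 ± 24.5 TPM in DKO and 2.55 ± 0.927 in WT cells (7.40 ± 0.18, adjusted p = 2.27e-08), and Apoe was 845 ± 68.1 and 19.4 ± 4.42 (5.39 ± 0.15, adjusted p = 2.27e-08). Epcam was 4.63 ± 1.22 TPM in DKO and 96.8 ± 30.7 in WT (-4.10 ± 0.21), and Krt19 was 172 ± 20.2 and 1119 ± 24.1 (-2.70 ± 0.10). The cell cycle, lower in steady state, hardly differed here.

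The other highest changes were in C1qc (6.66 ± 0.25), Pianp (6.34 ± 0.17), C1qa (6.01 ± 0.20), the matrix co-receptor Sdc4 (4.83 ± 0.27), the calcium-binding protein gene Chp2, with 323 reads in DKO and 0 in WT libraries (at least 149-fold higher, or 66.6-fold with 1 library left out), the transcription factor Sox4 (4.57 ± 0.15), the potassium channel Kcnj10 (4.50 ± 0.12), the prostaglandin synthase Hpgds (4.46 ± 0.23), Gas7 (4.45 ± 0.20) and Igf2r (4.34 ± 0.12). The lowest, after Epcam, were in the peroxisomal thiolase Acaa1b (-3.39 ± 0.24), Igkc (-3.21 ± 0.73), Vstm2a (-3.02 ± 0.22), the neuropeptide Gal (-2.84 ± 0.12), Fam189a2 (-2.79 ± 0.17), Fam89a (-2.71 ± 0.13), Krt19, the feature IMP_IDC_134 (-2.65 ± 0.52), the membrane protein Prom1 (-2.52 ± 0.12), the protease Ctse (-2.46 ± 0.18) and the small RNA Snord49b. Ctse lies near Ptprc, which encodes the CD45 antigen that told the genotypes apart, and rests on 7 reads in DKO and 222 in WT. IMP_IDC_134 had 1 and 76 reads, a ratio of 0.0182 (0.000454 to 0.104, and 0.0736 without DKO replicate 2), and Igkc, an immunoglobulin light chain of B cells, had 6 and 121. Snord49b (adjusted p = 0.048) had 0 and 3 reads in the DKO libraries and 9 and 5 in WT, too few for a fold.

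Of the macrophage markers in chimeras, those of interstitial macrophages and monocytes gave 13 higher, 2 lower and 7 not passing of 22, or 13 and 2 adjusted over the list alone and 13 and 2 after rescaling. Camera on interstitial and monocyte markers gave adjusted p = 2.61e-07, and adjusted p = 0.19 with an estimated correlation. C1qa, C1qb, C1qc and Apoe are again among its higher members. The fibronectin gene Fn1 (1.42 ± 0.12), Cx3cr1 (1.31 ± 0.14) and the transcription factor Maf (1.42 ± 0.16) were higher, and Cd163, with 7 and 84 reads, was lower. Peritoneal markers gave 9 higher, 0 lower and 12 not passing of 21, or 10 and 0 adjusted over the list alone and 9 and 0 after rescaling, with Cd93 at 2.58 ± 0.20 and the integrin Itga6 at 0.77 ± 0.12. Camera on peritoneal markers gave adjusted p = 0.000551, and adjusted p = 0.382 with an estimated correlation. Lysosomal and phagocytic genes gave 16 higher, 0 lower and 11 not passing of 27, or 18 and 0 adjusted over the list alone and 16 and 0 after rescaling, with Marco (2.99 ± 0.22), Msr1 (1.71 ± 0.13) and the protease Ctss (0.98 ± 0.08). Camera on lysosomal genes gave adjusted p = 4.91e-08, and adjusted p = 0.19 with an estimated correlation. Growth factor and cytokine receptors gave 14 higher, 2 lower and 6 not passing of 22, or 16 and 2 adjusted over the list alone and 14 and 2 after rescaling, with Csf3r at 2.67 ± 0.19. Camera on receptor genes gave adjusted p = 0.000551, and adjusted p = 0.382 with an estimated correlation. Genes of cholesterol synthesis gave 13 higher, 1 lower and 8 not passing of 22, or 15 and 1 adjusted over the list alone and 13 and 0 after rescaling. Camera on cholesterol synthesis gave adjusted p = 3.47e-05, and adjusted p = 0.382 with an estimated correlation. The squalene epoxidase Sqle rose by 0.87 ± 0.16. Inflammatory cytokines and NF-kB targets gave 10 higher, 0 lower and 10 not passing of 20, or 12 and 0 adjusted over the list alone and 10 and 0 after rescaling, among them the inhibitors Tnfaip3 (0.79 ± 0.11) and Nfkbia (1.02 ± 0.20), the cytokine Il6 (2.15 ± 0.51), and the cyclooxygenase Ptgs2 (2.55 ± 0.29), which lies near Ptprc. Camera on inflammatory genes gave adjusted p = 0.000551, and adjusted p = 0.251 with an estimated correlation. Of 10 dendritic cell markers, a list that did not pass, 4 were higher and 0 lower in the same libraries (adjusted p = 0.0734, and adjusted p = 0.382 with an estimated correlation), among them Itgae, at 7.63 and 1.56 TPM in DKO and 0.0572 and 0.0925 in WT, and Ccr7, at 4.46 and 2.64 in DKO and 0.662 and 0.321 in WT. Matrix genes and proteases gave 7 higher, 1 lower and 9 not passing of 17, or 9 and 2 adjusted over the list alone and 6 and 1 after rescaling, with Thbs1 at 3.98 ± 0.35 and Adam8 at 2.51 ± 0.22. Camera on matrix genes gave adjusted p = 0.0159, and adjusted p = 0.383 with an estimated correlation.

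Markers of lung epithelium were the list that fell in chimeras, with 0 higher, 6 lower and 3 not passing of 9, or 0 and 7 adjusted over the list alone and 0 and 6 after rescaling. Camera on epithelial markers gave adjusted p = 0.000551, and adjusted p = 0.382 with an estimated correlation. Beside Epcam, the surfactant protein gene Sftpc was 20.4 ± 8.96 TPM in DKO and 60.9 ± 14.4 in WT, and the club cell secretory gene Scgb1a1 20.8 ± 0.368 and 41.4 ± 3.54. The remaining lists did not pass. Higher and lower genes, with differing counts after rescaling in brackets, numbered 7 and 10 (7 and 9) for alveolar markers, 5 and 2 for microglia, 3 and 4 for Kupffer cells and splenic macrophages, 8 and 2 for transcription factors, 0 and 1 for S phase, 0 and 1 (0 and 2) for mitosis and 3 and 2 for inhibitors of the cell cycle. They numbered 4 and 3 for LXR targets, 3 and 5 for fatty acid handling, 6 and 0 (6 and 1) for chemokines, 5 and 1 (4 and 1) for interferon, 1 and 3 for MHC class II, 1 and 1 (2 and 1) for the clock, 5 and 5 for hypoxia and glycolysis and 3 and 0 for immediate-early genes. They numbered 2 and 0 for B cells, 1 and 0 for neutrophils, 4 and 0 for dendritic cells and 1 and 2 for endothelium and fibroblasts. Of the lists too small to test, Lat was 7.71 and 6.24 TPM in DKO and 2.65 and 2.91 in WT, opposite to its fall in steady state, and Pf4 was 8.39 and 15.6 in DKO and 10.9 and 8.99 in WT. Dendritic cells had the smallest adjusted p among these, 0.0734, and immediate-early genes the largest, 0.943. For LXR targets, hypoxia and neutrophils the median lay below that of all genes and the mean above it, for fatty acid handling the median above and the mean below, and for immediate-early genes camera pointed up while both lay below.

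In chimeras 3354 genes passed, 1686 higher and 1668 lower, or 1763 and 1859 of 3622 after rescaling. Of these, 454 were higher and 185 lower by at least 2-fold, or 448 and 193 after rescaling. The count rested in part on single libraries. It was 2034 without WT replicate 1, 2160 without WT replicate 2 and 2000 without DKO replicate 1, the library with the lowest depth.

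The changes of all 12303 genes in steady state and in chimeras had a Pearson correlation of 0.615 and a Spearman correlation of 0.459 across genes, which are not independent replicates. Of the genes that passed in both, 894 were higher in both where independence would give 204.9, 1185 were lower in both where it would give 656.5, and 166 went opposite ways where it would give 866.2. After rescaling the correlation was 0.607, with 1110 higher and 762 lower in both. The correlation with the peritoneal changes was 0.18 for steady state and 0.186 for chimeras.

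**Figure D2:**
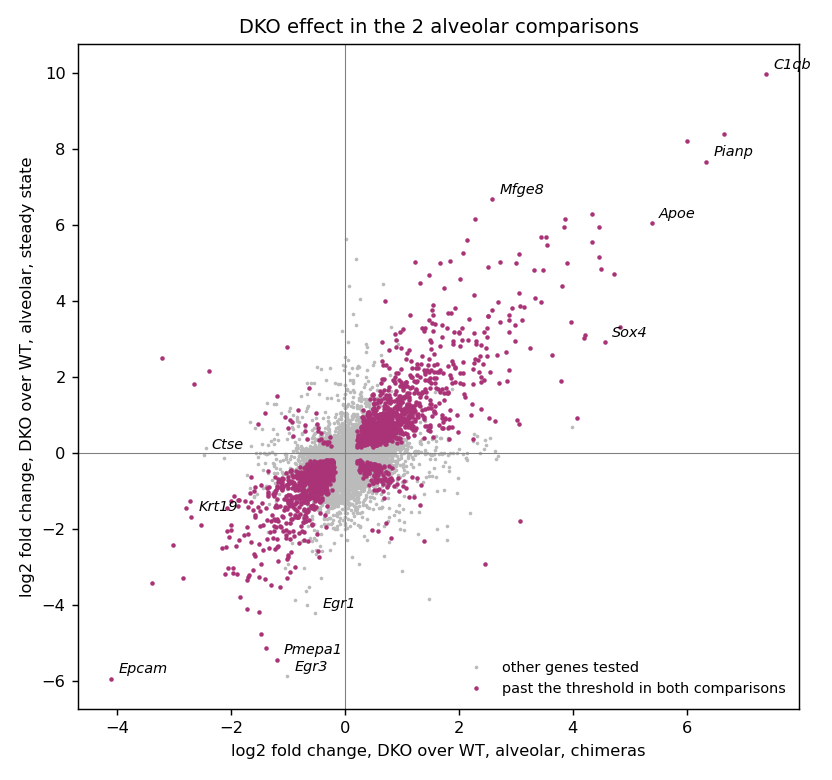
Log2 fold change of DKO over WT in steady-state alveolar macrophages (y axis) and in alveolar macrophages of mixed chimeras (x axis), a point for each of 12303 genes, coloured where a gene passed in both comparisons. C1qb, Apoe and Pianp lie high on both axes and Epcam low on both, while Egr1, Egr3 and Pmepa1 are much lower in steady state than in chimeras.

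The interaction of genotype with setting asks whether the DKO change itself differed between chimeras and steady state. It passed for 3000 genes, 2444 with a higher and 556 with a lower change in chimeras, or 835 and 1250 of 2085 after rescaling. The count was 1574 without WT steady-state replicate 1, 1040 without WT steady-state replicate 2, 1720 without DKO steady-state replicate 2, 1389 without WT chimera replicate 1, 1973 without WT chimera replicate 2 and 1765 without DKO chimera replicate 1. The largest positive differences were in Egr3 (4.85 ± 0.51), Pmepa1 (4.23 ± 0.15), Uck2 (3.74 ± 0.21) and the small RNAs Snord58b and Snord69. Snord58b had 3 reads over the 4 chimera libraries and Snord69 had 4, too few for a fold, and Snord69 no longer passed after rescaling. The largest negative ones were in Igkc (-5.72 ± 1.03), Saa3 (-5.62 ± 0.69), the matricellular gene Nov (-4.91 ± 0.38), the immunoglobulin gene IGHA (-4.54 ± 1.02) and IMP_IDC_134 (-4.48 ± 0.74). Over all 4 chimera libraries Saa3 and Nov had 4 reads each, so their differences mostly restate the rise in steady state. Igkc had 14.7 and 89.44 TPM in DKO and 3.773 and 8.192 in WT steady-state libraries, and 1.091 and 1.753 in DKO and 17.82 and 25.21 in WT chimera libraries. In steady state the ratio of read shares for IGHA, 8.32, was 2.24 without DKO replicate 2 and 132 without WT replicate 2. For IMP_IDC_134 it was 4.41, or 2.08 without WT replicate 1 and at least 10.9 without WT replicate 2. The library numbers differ between settings, so setting and library series cannot be separated in this comparison.

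Peritoneal macrophages carry the same mutations in a cell that has little Bhlhe41 of its own, and the comparison asks whether the genes act alike there. DKO peritoneal macrophages differed most in other genes than alveolar ones. The calcium-binding protein gene Rcn3 went from 10.4 ± 1.66 to 366 ± 76.8 TPM (4.995, adjusted p = 1.98e-07). The immediate-early gene Fos went from 15 to 140.0 TPM (3.14 ± 0.15, adjusted p = 2.08e-06). The lipoprotein lipase Lpl, which frees fatty acids for uptake, fell from 540.1 ± 89.4 to 48.2 ± 9.04 TPM (-3.46 ± 0.13, adjusted p = 5.77e-07). Spp1, the secreted matrix protein osteopontin, had 2 reads in DKO and 561 in WT libraries, a ratio of 0.00389 (0.00047 to 0.0141). The WT libraries were uneven, at 7.265 and 24.33 TPM, and with 1 library left out the ratio ran from 0.00238 to 0.00791. C1qb and Apoe, abundant already in WT cells, changed by 0.50 ± 0.18 (adjusted p = 0.0741) and 0.75 ± 0.15 (adjusted p = 0.00602).

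After Rcn3, the highest changes were in Bhlhe41, the secreted peptide gene Prok2 (4.17 ± 0.13) and the semaphorin receptor Plxnd1 (3.15 ± 0.13), both near Bhlhe40, in Plac8 (3.24 ± 0.24), the adhesion gene Tns1 (3.15 ± 0.17), Fos, Srpx (3.05 ± 0.25), the calcium-responsive transcription factor Nfatc2 (2.90 ± 0.18), Snhg11 (2.89 ± 0.23), the membrane protein Emp1 (2.85 ± 0.09), which lies near Bhlhe41, and the folate receptor Folr2 (2.76 ± 0.28). The lowest, after Spp1 and Lpl, were in Stard13 (-3.42 ± 0.14), the protease Prtn3 (-3.09 ± 0.23), Glipr2 (-3.01 ± 0.17), the actin-binding Coro1a (-3.01 ± 0.13), Emb (0.467 against 10.8 TPM), the caveolin Cav1 (-2.77 ± 0.32), the inhibitor of DNA binding Id2 (25.9 against 165 TPM), Pi16 (-2.60 ± 0.19), the antibacterial Pglyrp1 (-2.56 ± 0.42) and the ubiquitin ligase Nedd4 (-2.52 ± 0.25). Over the chimera libraries Prok2 had 0 reads and Srpx 1, and both had 0 over the steady-state alveolar ones. The spread of such genes comes almost only from the peritoneal libraries, so their SE may be too small.

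Interferon-response genes rose most uniformly in peritoneal macrophages, with 21 higher, 0 lower and 7 not passing of 28, or 22 and 0 adjusted over the list alone and 21 and 0 after rescaling. Camera on interferon-response genes gave adjusted p = 1.14e-17, and adjusted p = 0.0838 with an estimated correlation. Higher interferon-response genes included Irf7 (2.29 ± 0.12) and the antiviral Oasl1 (2.41 ± 0.25). Immediate-early and heat shock genes, lower in steady-state alveolar DKO cells, gave 11 higher, 0 lower and 13 not passing of 24, or 15 and 1 adjusted over the list alone and 11 and 0 after rescaling. Camera on immediate-early genes gave adjusted p = 4.85e-10, and adjusted p = 0.11 with an estimated correlation. Beside Fos, the phosphatase Dusp1 rose by 2.44 ± 0.26, Fosb by 2.42 ± 0.39 and Jun by 1.08 ± 0.24. Lysosomal and phagocytic genes gave 11 higher, 0 lower and 16 not passing of 27, or 14 and 1 adjusted over the list alone and 14 and 0 after rescaling, with Ctsb (0.94 ± 0.11) and Axl, a receptor for dying cells (1.39 ± 0.20). Camera on lysosomal genes gave adjusted p = 4.67e-08, and adjusted p = 0.11 with an estimated correlation. Genes of the circadian clock, of which Bhlhe40 and Bhlhe41 are themselves a part, gave 10 higher, 2 lower and 6 not passing of 18, or 11 and 2 adjusted over the list alone and 12 and 2 after rescaling. Camera on clock genes gave adjusted p = 5.51e-06, and adjusted p = 0.251 with an estimated correlation. Per2 (1.93 ± 0.19) and Cry1 (1.21 ± 0.18) were higher, and their activator Arntl (-1.42 ± 0.20) and Nfil3 (-1.88 ± 0.32) were lower. Kupffer cell and splenic markers gave 5 higher, 1 lower and 8 not passing of 14, or 6 and 1 adjusted over the list alone and 6 and 1 after rescaling, with Fcna at 1.95 ± 0.18 and Vsig4 at 1.11 ± 0.18. Camera on Kupffer and splenic markers gave adjusted p = 4.99e-05, and adjusted p = 0.0838 with an estimated correlation. LXR targets gave 7 higher, 4 lower and 4 not passing of 15, or 7 and 4 adjusted over the list alone and 8 and 3 after rescaling, with Pltp (1.26 ± 0.12) and Nr1h3 (1.41 ± 0.14). Camera on LXR targets gave adjusted p = 0.00448, and adjusted p = 0.11 with an estimated correlation.

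S phase genes fell in peritoneal DKO cells, with 0 higher, 22 lower and 6 not passing of 28, or 0 and 28 adjusted over the list alone and 0 and 20 after rescaling, among them Mcm5 (-1.39 ± 0.15) and Mcm2 (-1.21 ± 0.16), which lies near Bhlhe40. Camera on S phase genes gave adjusted p = 1.2e-10, and adjusted p = 0.27 with an estimated correlation. Genes of mitosis gave 0 higher, 18 lower and 10 not passing of 28, or 0 and 24 adjusted over the list alone and 0 and 14 after rescaling, with Cdc20 (-1.21 ± 0.16) and Plk1 (-1.16 ± 0.16). Camera on genes of mitosis gave adjusted p = 2.1e-07, and adjusted p = 0.405 with an estimated correlation. Cholesterol synthesis gave 1 higher, 7 lower and 14 not passing of 22, or 1 and 11 adjusted over the list alone and 1 and 2 after rescaling, with Sc5d at -0.44 ± 0.08 and Insig1 at 0.98 ± 0.20. Camera on cholesterol synthesis gave adjusted p = 0.0481, and adjusted p = 0.529 with an estimated correlation. Interstitial markers gave 8 higher, 3 lower and 11 not passing of 22, or 11 and 6 adjusted over the list alone and 10 and 3 after rescaling, with Lyve1 (1.61 ± 0.25) higher and Vcan (-2.07 ± 0.16) lower. Camera on interstitial and monocyte markers gave adjusted p = 0.00789, and adjusted p = 0.236 with an estimated correlation. Macrophage transcription factors gave 7 higher, 5 lower and 14 not passing of 26, or 8 and 5 adjusted over the list alone and 9 and 5 after rescaling. Camera on transcription factors gave adjusted p = 0.0133, and adjusted p = 0.27 with an estimated correlation. Pparg (1.79 ± 0.15), near Bhlhe40, and Id3 (22.7 against 7.9 TPM) were higher, and Gata6 (-0.81 ± 0.14) was lower. Growth factor and cytokine receptors gave 7 higher, 5 lower and 10 not passing of 22, or 9 and 6 adjusted over the list alone and 9 and 2 after rescaling, with Il10rb at 0.59 ± 0.07. Camera on receptor genes gave adjusted p = 0.0327, and adjusted p = 0.464 with an estimated correlation. Chemokines gave 4 higher, 2 lower and 16 not passing of 22, or 4 and 2 adjusted over the list alone and 4 and 2 after rescaling, with Cxcl2 at 0.98 ± 0.21. Camera on chemokine genes gave adjusted p = 0.00808, and adjusted p = 0.235 with an estimated correlation. Inflammatory cytokines and NF-kB targets gave 4 higher, 2 lower and 14 not passing of 20, or 4 and 2 adjusted over the list alone and 5 and 2 after rescaling, with Nfkbiz at 1.31 ± 0.24. Camera on inflammatory genes gave adjusted p = 0.00324, and adjusted p = 0.208 with an estimated correlation. MHC class II genes gave 4 higher, 0 lower and 7 not passing of 11, or 4 and 0 adjusted over the list alone and 4 and 0 after rescaling, with H2-Aa at 1.98 ± 0.41 and Cd74 at 1.79 ± 0.43. Camera on MHC class II genes gave adjusted p = 0.00858, and adjusted p = 0.464 with an estimated correlation.

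The markers of the peritoneal macrophage itself did not pass as a list, with 2 higher, 11 lower and 8 not passing of 21, or 2 and 12 adjusted over the list alone and 2 and 11 after rescaling. Camera on peritoneal markers gave adjusted p = 0.0519, and adjusted p = 0.464 with an estimated correlation. Serpinb2 (-2.35 ± 0.11), Garnl3 (-1.61 ± 0.18) and Alox15 (-0.58 ± 0.11) were lower. In the other lists that did not pass, higher and lower genes, again with rescaled counts in brackets where they differ, numbered 4 and 5 (4 and 4) for alveolar markers, 2 and 2 (2 and 1) for microglia, 1 and 6 (1 and 1) for inhibitors of the cell cycle, 2 and 5 (3 and 5) for fatty acid handling, 1 and 7 (1 and 5) for hypoxia and glycolysis and 2 and 3 for matrix genes. They numbered 1 and 0 for lung epithelium, 0 and 0 for B cells, 0 and 3 (0 and 2) for neutrophils, 1 and 3 (1 and 2) for dendritic cells and 0 and 1 for endothelium and fibroblasts. The mast cell and basophil gene Hdc, counted with neutrophils, was 25.9 ± 9.02 TPM in DKO and 109 ± 2.46 in WT. Adjusted p ran from 0.0519 for hypoxia to 0.944 for B cells. For alveolar markers, B cells and endothelium the median lay above that of all genes and the mean below it.

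In peritoneal macrophages 2813 genes passed, 837 higher and 1976 lower, or 1464 and 968 of 2432 after rescaling. Of these, 207 were higher and 228 lower by at least 2-fold, or 261 and 167 after rescaling. Each library weighed on the count, which was 1619 without WT replicate 1, 1236 without WT replicate 2, 1588 without DKO replicate 1 and 1644 without DKO replicate 2.

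**Figure D3:**
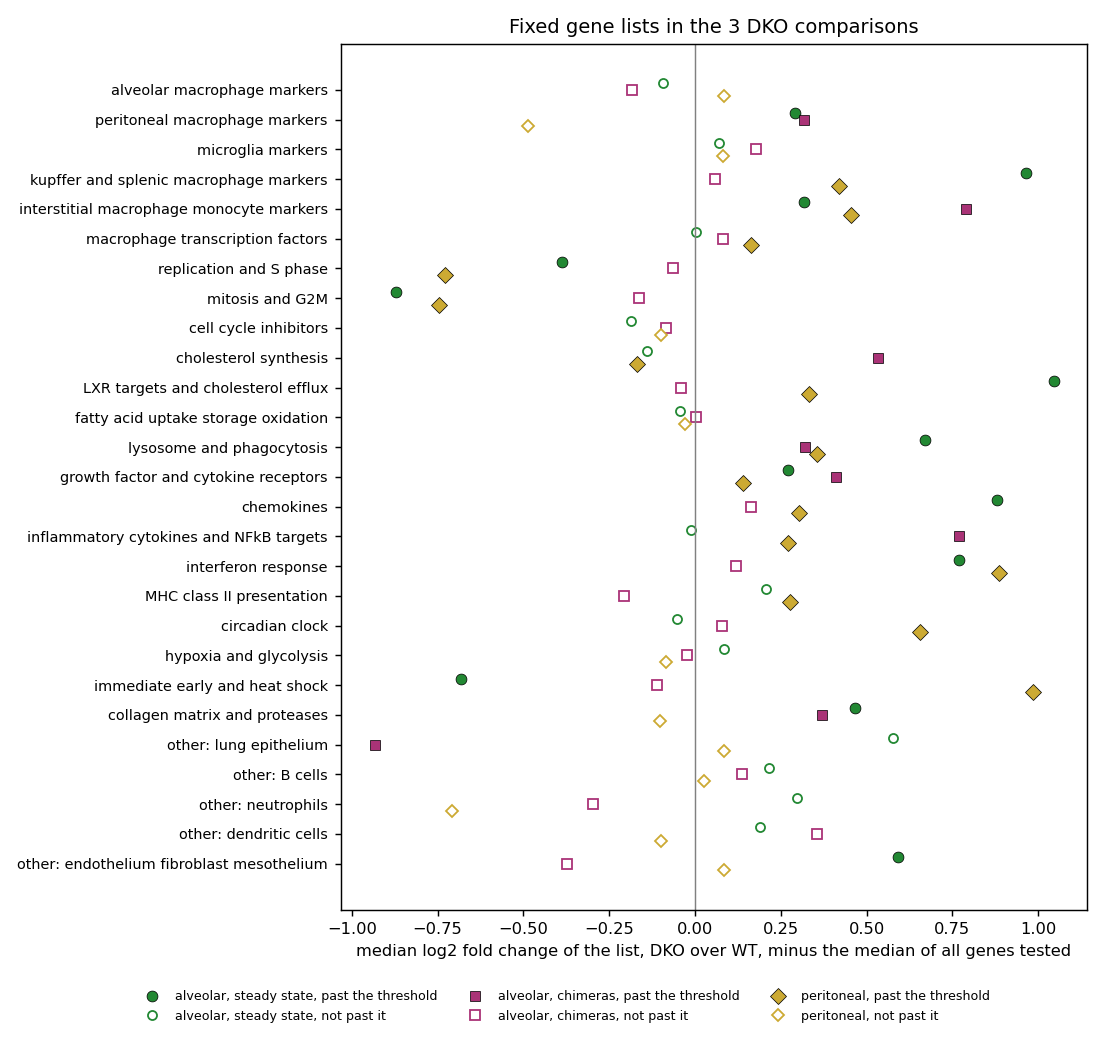
Median log2 fold change of DKO over WT, relative to the median of all genes, for 27 gene lists (vertical axis) in steady-state alveolar, chimera alveolar and peritoneal macrophages, with filled points for lists past the threshold. Immediate-early genes lie below all genes in steady state and above them in the peritoneum, and lysosomal genes lie above in all 3.

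The interaction of genotype with tissue asks whether the DKO change differed between peritoneal and steady-state alveolar macrophages. It passed for 3480 genes, 2129 with a higher and 1351 with a lower change in the peritoneum, or 1668 and 1702 of 3370 after rescaling. The count was 2171 without WT steady-state replicate 2 and 2134 without WT peritoneal replicate 2. The largest positive differences were in Egr3 (6.65 ± 0.51), Pmepa1 (6.23 ± 0.15), Egr1 (6.15 ± 1.02), Epcam (5.90 ± 0.30) and Fosb (4.85 ± 0.55). The largest negative ones were in C1qb (-9.46 ± 0.26), C1qc (-7.86 ± 0.36), C1qa (-7.49 ± 0.28), Mfge8 (-7.41 ± 0.48) and Pianp (-6.79 ± 0.25). Epcam had 1 read over all 4 peritoneal libraries, so its difference mostly restates the alveolar fall. Egr1 was uneven between the DKO peritoneal libraries, at 94.8 ± 96.1 TPM. Tissue and library series cannot be separated in this comparison.

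**Figure D4:**
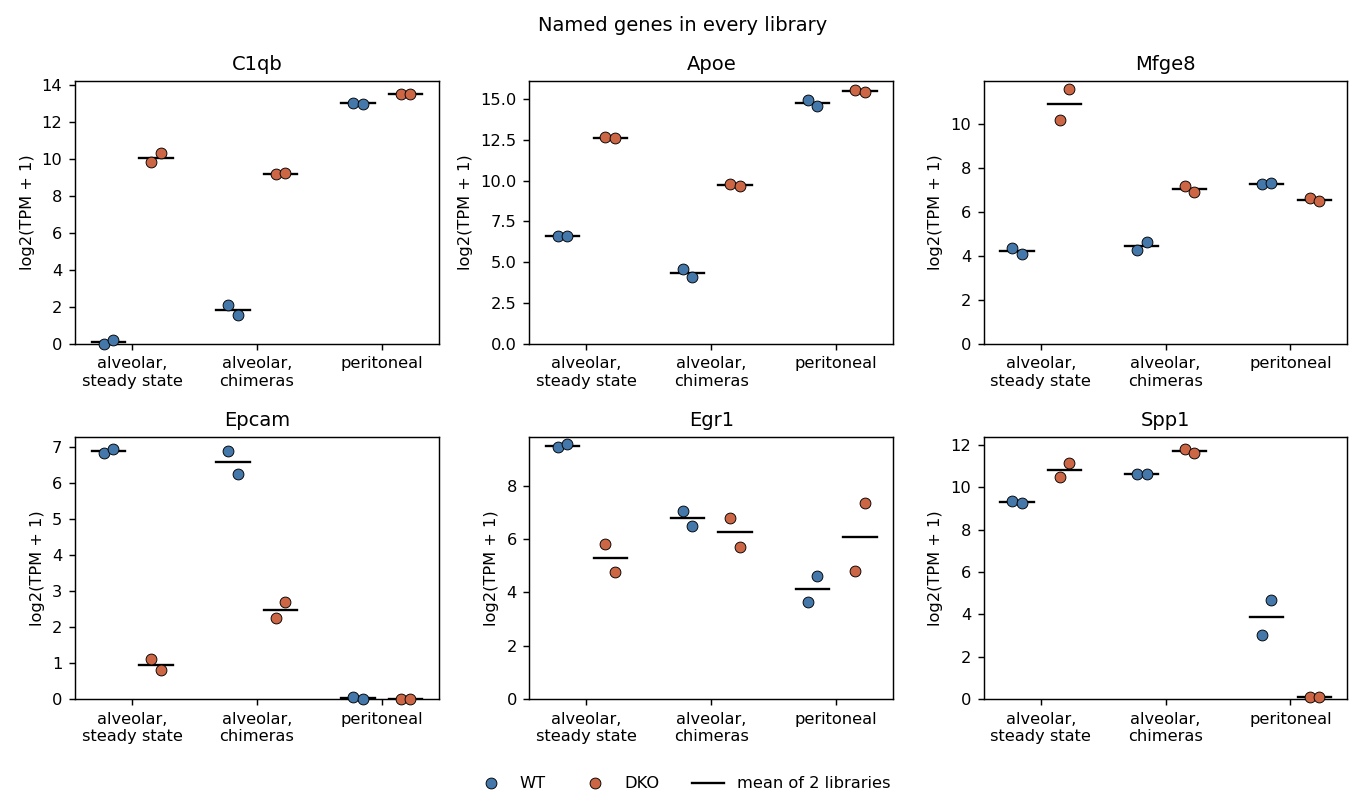
Values of C1qb, Apoe, Mfge8, Epcam, Egr1 and Spp1 in each of the 12 libraries, by population and genotype, as log2(TPM + 1). C1qb and Apoe are higher in DKO alveolar libraries of both settings, Egr1 is lower in DKO than in WT at steady state, and Spp1 is lower in DKO peritoneal libraries.

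The tissue signature asks whether DKO alveolar macrophages moved toward the peritoneal type. Of 844 genes higher in WT peritoneal than in WT chimera alveolar macrophages, 315 were higher and 82 lower in DKO steady-state cells, or 365 and 41 after rescaling. The share that was higher was 37.3%, against 9.9% of the other genes (adjusted p = 1.13e-23, and adjusted p = 0.00494 with an estimated correlation). In chimeras 306 of 745 such genes, picked with the steady-state WT libraries, were higher and 27 lower, or 305 and 28 after rescaling. The share was 41.1%, against 11.8% of the other genes (adjusted p = 2.83e-16, and adjusted p = 0.0149 with an estimated correlation). Many of these genes, such as Alox15 and Wnt2, were at or near 0 TPM in WT alveolar libraries and entered through the peritoneal ones. Such genes can rise but hardly fall, so the excess of higher over lower genes is in part set by the floor. The other genes were not matched for level, and the fixed peritoneal markers share this limit in alveolar cells. Of genes higher in WT alveolar cells, in steady state 409 of 746 were lower and 116 higher, or 305 and 167 after rescaling, a share of 54.8% against 40.6% of the other genes (adjusted p = 0.0135, and adjusted p = 0.421 with an estimated correlation). In chimeras 258 of 909 were lower and 121 higher, or 273 and 125 after rescaling, a share of 28.4% against 13% (adjusted p = 0.000711, and adjusted p = 0.35 with an estimated correlation).

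In the authors' deposited table, 4615 genes passed in steady state (2502 higher and 2113 lower), 2751 in chimeras (1468 and 1283) and 3948 in the peritoneum (2119 and 1829). Genes passing in both the limma fit and the authors' deposited table with the same sign numbered 3484, 2401 and 2359, or 4116, 2463 and 2350 after rescaling. Over all genes compared, the sign was the same for 78.9%, 97.1% and 84.9%, or 99.5%, 97.9% and 96% after rescaling. Of the authors' calls 54.2%, 53.4% and 53.7% were higher. In the limma fit the shares were 23.6%, 50.3% and 29.8%, or 53.3%, 48.7% and 60.2% after rescaling. Genes named here only as members of a list or of the tissue comparison were chosen after their values were seen.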

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

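The tests of peritoneal-type cells, of interstitial macrophages or monocytes, of the genotype within the same host and of a genotype effect common to both alveolar settings were chosen after the results they measure were seen. Differences between the DKO changes of populations were taken from the interaction terms of the limma fit at adjusted p under 0.05. The change of DKO over WT differed between chimeras and steady-state alveolar macrophages for 3000 genes, of which 2444 had a higher change in chimeras (835 of 2085 after rescaling). The count was 1574 without WT steady-state replicate 1, 1040 without WT steady-state replicate 2, 1720 without DKO steady-state replicate 2, 1389 without WT chimera replicate 1, 1973 without WT chimera replicate 2 and 1765 without DKO chimera replicate 1. Among the genes named above, the log2 change was lower in chimeras for Igkc (-5.72), Saa3 (-5.62), Nov (-4.91), IGHA (-4.54), IMP_IDC_134 (-4.48), Mfge8 (-4.09), Tmem37 (-3.87), C1qb (-2.57), Ctse (-2.42), Htra4 (-2.28), C1qa (-2.2), Cmklr1 (-2.16), Pmp22 (-2.1), Igf2r (-1.96), C1qc (-1.72), Gas7 (-1.48), Fam89a (-1.45), Fam189a2 (-1.34), Pianp (-1.33), Krt19 (-1.02), Apoe (-0.65) and Prom1 (-0.63). It was higher in chimeras for Sdc4 (1.52), Sox4 (1.66), Epcam (1.83), G0s2 (1.94), Areg (2.38), Vash1 (2.66), Spag11b (3.29), Scarna9 (3.35), Egr1 (3.69), Uck2 (3.74), Snord69 (4.08), Pmepa1 (4.23), Egr3 (4.85) and Snord58b (5.3). The largest adjusted p among these was 0.0459. Snord69 no longer passed after rescaling, and the small RNAs rest on few reads (3 for Snord58b, 4 for Snord69 and 19 for Scarna9 over the chimera libraries), so their values are not folds to rely on. Saa3 and Nov had 4 reads each over the chimera libraries and Ctse 5 over the steady-state ones, so their differences mostly restate the change in the other setting. Igkc, IGHA and IMP_IDC_134 were uneven between steady-state libraries of the same genotype.

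The change was lower in chimeras, relative to all genes, for the lists of Kupffer and splenic markers (-1.034, with 2 higher and 7 lower genes of 14, 2 and 7 after rescaling, adjusted p = 8.75e-06 and 0.027), interstitial and monocyte markers (-0.225, with 4 higher and 5 lower genes of 22, 4 and 6 after rescaling, adjusted p = 0.0344 and 0.376), LXR targets (-0.866, with 1 higher and 10 lower genes of 15, 0 and 11 after rescaling, adjusted p = 1.14e-09 and 0.011), lysosomal genes (-0.26, with 1 higher and 5 lower genes of 27, 0 and 6 after rescaling, adjusted p = 0.001 and 0.317), chemokines (-0.578, with 3 higher and 6 lower genes of 22, 2 and 5 after rescaling, adjusted p = 0.00987 and 0.317), interferon-response genes (-0.538, with 0 higher and 4 lower genes of 28, 0 and 7 after rescaling, adjusted p = 2.47e-08 and 0.291), matrix genes (-0.596, with 3 higher and 5 lower genes of 17, 3 and 5 after rescaling, adjusted p = 0.0204 and 0.416), lung epithelium (-1.222, with 1 higher and 4 lower genes of 9, 1 and 4 after rescaling, adjusted p = 0.001 and 0.337) and endothelium and fibroblasts (-1.101, with 1 higher and 2 lower genes of 5, 1 and 4 after rescaling, adjusted p = 0.0012 and 0.317). It was higher for S phase genes (0.382, with 14 higher and 0 lower genes of 28, 3 and 0 after rescaling, adjusted p = 0.0039 and 0.612), genes of mitosis (0.611, with 10 higher and 0 lower genes of 28, 3 and 0 after rescaling, adjusted p = 0.00112 and 0.612), cholesterol synthesis (0.704, with 14 higher and 0 lower genes of 22, 11 and 0 after rescaling, adjusted p = 3.34e-05 and 0.317) and immediate-early genes (0.833, with 12 higher and 0 lower genes of 24, 9 and 0 after rescaling, adjusted p = 0.00295 and 0.412). In each bracket the value is the median difference, and the later p is that with an estimated correlation, under which Kupffer and splenic markers and LXR targets passed.

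Between peritoneal and steady-state alveolar macrophages the change differed for 3480 genes, of which 2129 had a higher change in the peritoneum (1668 of 3370 after rescaling). The count was 2171 without WT steady-state replicate 2 and 2134 without WT peritoneal replicate 2. The log2 change was lower in the peritoneum for C1qb (-9.46), C1qc (-7.86), C1qa (-7.49), Mfge8 (-7.41), Pianp (-6.79), Igf2r (-5.81), Gas7 (-5.69), Cmklr1 (-5.59), Pmp22 (-5.5), Apoe (-5.3), Htra4 (-5.29), Spp1 (-5.28), Tmem37 (-4.92), Lpl (-4.04), Emb (-3.49), Id2 (-3.45), Stard13 (-3.39), Prtn3 (-3.17), Cav1 (-2.72), Pglyrp1 (-2.65), Nedd4 (-2.49), Pi16 (-2.3), Coro1a (-1.5) and Glipr2 (-0.75). It was higher there for Emp1 (1.57), Snhg11 (1.99), Plxnd1 (2.11), Nfatc2 (2.13), Folr2 (2.69), Srpx (3.05), Rcn3 (3.17), Snord58b (3.42), Tns1 (3.42), Bhlhe41 (3.53), Fos (3.55), G0s2 (3.94), Scarna9 (4), Plac8 (4.12), Areg (4.16), Prok2 (4.17), Vash1 (4.24), Uck2 (4.39), Nr4a3 (4.65), Spag11b (4.76), Fosb (4.85), Epcam (5.9), Egr1 (6.15), Pmepa1 (6.23) and Egr3 (6.65). The largest adjusted p among these was 0.0446. Egr1 was uneven between the DKO peritoneal libraries. Some genes with at most 10 reads in a population mostly restate the change in the other. Spag11b and Scarna9 had 0 reads, Epcam 1 and Areg 3 over the 4 peritoneal libraries. Over the 4 steady-state alveolar ones Srpx and Prok2 had 0, Prtn3 1, Pglyrp1 5, Stard13 6, Folr2 7, Plac8 9 and Pi16 10. Snord58b had 13 reads over the steady-state and 12 over the peritoneal libraries, too few for a fold. The lists with a lower change in the peritoneum were peritoneal markers (-1.075, with 0 higher and 16 lower genes of 21, 0 and 12 after rescaling, adjusted p = 3.59e-09 and 0.132), interstitial and monocyte markers (-0.755, with 5 higher and 12 lower genes of 22, 5 and 12 after rescaling, adjusted p = 0.000107 and 0.14), S phase genes (-0.29, with 1 higher and 3 lower genes of 28, 1 and 4 after rescaling, adjusted p = 0.042 and 0.795), LXR targets (-0.649, with 3 higher and 8 lower genes of 15, 1 and 8 after rescaling, adjusted p = 0.00101 and 0.132), lysosomal genes (-0.37, with 3 higher and 11 lower genes of 27, 2 and 12 after rescaling, adjusted p = 0.000716 and 0.28), matrix genes (-0.719, with 2 higher and 9 lower genes of 17, 1 and 9 after rescaling, adjusted p = 0.000559 and 0.28), neutrophils (-1.965, with 1 higher and 4 lower genes of 5, 1 and 4 after rescaling, adjusted p = 0.00344 and 0.132) and endothelium and fibroblasts (-0.631, with 0 higher and 2 lower genes of 5, 0 and 2 after rescaling, adjusted p = 0.017 and 0.391). Those with a higher change were clock genes (0.556, with 8 higher and 0 lower genes of 18, 8 and 1 after rescaling, adjusted p = 0.017 and 0.672) and immediate-early genes (1.68, with 18 higher and 0 lower genes of 24, 17 and 0 after rescaling, adjusted p = 1.38e-07 and 0.185). None of these lists passed with an estimated correlation. Library series and population cannot be separated in either interaction.

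C1q genes, Apoe and other genes of peritoneal macrophages were higher in DKO alveolar macrophages. The tables argue against peritoneal-type cells in the sort: the median share of 113 abundant peritoneal-high genes in steady state, and 112 in chimeras, was at most 0.13 of the share the C1q genes reached, where a bound of 0.25 was set after a first bound of 0.1 had been missed in chimeras, and Alox15, at 8356 TPM in WT peritoneal cells, was 0.052 TPM in DKO steady-state cells. Interstitial macrophages or monocytes stay open, since 59.1% of their markers (13 of 22) were higher in chimeras and 40.9% in steady state, between the bounds set. How many of them the CD11c+ SiglecF+ CD11b low gate let through was not measured here. That list holds C1qa, C1qb, C1qc and Apoe, the genes whose rise is to be explained. Part of each share was therefore given in advance, and the shares do not speak for such cells. The peritoneal-high set moved the same way in chimeras (camera adjusted p = 2.83e-16), although its members near the floor in WT alveolar cells could hardly fall. For the set as a whole, a change of DKO cells that does not need a DKO lung is therefore only a candidate explanation. For the C1q genes and Apoe, named from the steady-state libraries, the chimera values argue against a need for a DKO lung. There C1qb was 587 ± 24.5 TPM in DKO and 2.55 ± 0.927 in WT cells, and Apoe 845 ± 68.1 and 19.4 ± 4.42. C1qc (6.66 ± 0.25) and C1qa (6.01 ± 0.20) were higher there too. Cells that differ in number between the genotypes within the sorted gate were not tested.

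Immediate-early and heat shock genes, which also rise when cells are handled, were lower in DKO steady-state alveolar macrophages. A handling response in the WT steady-state libraries alone is argued against only for the median of the set, since the median member was 0.141 higher there than in WT chimera libraries (quartiles -0.185 to 0.651, and -0.091 after rescaling), while the median difference of DKO steady-state from DKO chimera libraries was -0.909. Members past the threshold went both ways between the WT groups, with 4 higher and 7 lower in chimeras, or 5 and 4 after rescaling. Hspa1a (2.96), Hspa1b (2.8) and Ier3 (1.14) were higher in chimeras. For members lower in WT chimera libraries a handling response stays open as a part of the difference. Among them were Egr1, Egr3, Btg2, Egr2 and Ier2 (-2.71, -2.3, -1.66, -1.28 and -1.16) and, less so, Jun, Fosb and Fos (-0.84, -0.59 and -0.53). All of these were also higher in DKO chimera than in DKO steady-state libraries, from 0.08 for Jun and 0.98 for Egr1 to 2.55 for Egr3. A genotype effect common to both settings is argued against too, since the median change in chimeras was 0.115 of that in steady state (-0.104 and -0.901). A state of the DKO steady-state libraries, from handling or from the DKO lung, may also contribute. This design cannot separate handling of either genotype from the DKO lung.

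Genes near the targeted loci changed more often than genes elsewhere. Among 168 neighbours of Bhlhe40 and Bhlhe41, 16.07%, 8.93% and 10.12% changed at least 2-fold in steady state, chimeras and peritoneum, above the 95th percentile of 10000 windows (13.69%, 8.33% and 6.55%) in 3 of 3 populations, as donor sequence around the targeted genes would give. By locus the shares were 23.53%, 13.24% and 13.24% at Bhlhe41, each above its own 95th percentile. At Bhlhe40 they were 11%, 6% and 8%, level with its 95th percentile of 8% in the peritoneum and below it in the others. The windows for Bhlhe40 had medians of 10%, 5% and 3%, so its shares in both alveolar comparisons were close to the median and show no excess. The loci were not tested against each other. Near Ptprc, where the WT chimera cells carry CD45.1 sequence, 12% changed in chimeras against a 95th percentile of 10%, and 7% and 3% in the other populations. The count takes changes of either sign, so it cannot tell donor sequence from an effect of the genotype on genes that lie together. In steady state, chimeras and peritoneum, Emp1 (1.285, 2.239 and 2.85) and Clec1b (-1.439, -2.07 and -1.199) kept their sign. Ldhb (0.112, 2.439 and -0.993) and Plbd1 (-0.162, 2.653 and -1.24) were higher in chimeras and lower in the peritoneum, and did not pass in steady state. Hebp1 (-0.031, -0.092 and 1.606) passed in the peritoneum only. Donor sequence may account for some of these genes, and an effect of the genotype on them stays open and was not tested.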

How the results depend on the processing

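The fit with voom weights on recovered reads was chosen after seeing the data. Of the tests of named genes, 1504 kept their direction and side of the threshold over the alternatives, 31 lost the threshold and 0 reversed. Of the list tests 1085 kept theirs, 74 lost and 45 gained the threshold, and 2 reversed: alveolar markers (adjusted p = 0.00728, down) and hypoxia and glycolysis (0.0409, down) in steady state under fry, which tests against no change and not against other genes. A minimum of 2-fold, which by construction calls fewer, left 1201 genes in steady state, 639 in chimeras, 435 in the peritoneum, 831 and 1249 in the chimera and peritoneal interactions and 3649 between the WT tissues. A fit on only the groups compared, which has fewer libraries, gave 4069 in steady state, 1608 in chimeras and 1206 in the chimera interaction. For that interaction quantile normalization gave 1833 and voom 1964; the cause was not tested. Under the other settings, libraries left out aside, counts ran from 4719 to 6325 in steady state, 3042 to 3622 in chimeras and 2189 to 2995 in the peritoneum. The authors' own calls numbered 4615, 2751 and 3948.

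Leaving out 1 library at a time gave 2000 to 3178 genes in chimeras, 1236 to 1644 in the peritoneum, 1040 to 4185 in the chimera interaction and 2134 to 4447 in the peritoneal interaction, and a steady-state to chimera correlation of 0.555 to 0.625. The lone library left in an arm is assumed to vary like the other groups, and fewer libraries lower the counts by construction. That does not account for the counts that rose, whose cause was not tested. With an estimated correlation, 1 list passed in steady state (13 before), 0 in chimeras (8) and 0 in the peritoneum (15), while fry gave 17 in chimeras. The alveolar-high set no longer passed with an estimated correlation (-0.373, adjusted p = 0.421, in steady state and -0.224, adjusted p = 0.35, in chimeras), nor in steady state with log2(TPM + 0.1) (-0.342, adjusted p = 0.374). That pseudocount also moved the correlation of steady state with chimeras to 0.508 and of chimeras with the peritoneum to 0.138, and log2(TPM + 5) moved the latter to 0.229; the cause was not tested. Genes with 0 reads in a group and more than 3 in the other were also placed at their bounds. The list median, relative to all genes, then went from 0.003 to -0.099 for transcription factors in steady state, from 0.355 to 0.645 for dendritic cells and 0.318 to 0.462 for peritoneal markers in chimeras, and from 0.27 to 0.342 for inflammatory genes in the peritoneum. Count models need counts and were not run on TPM. On the recovered reads, voom was the only such fit tried. DKO chimera replicate 1 had the lowest depth, 6.59 M reads, yet the most features above 0, 16173. How far its depth limits low genes was not tested.

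The replicate block gave 6064, 3072 and 2511 genes in steady state, chimeras and peritoneum, 2333 and 3043 in the interactions and 7649 between WT tissues. The labels give no pairing of libraries by number, and residuals of libraries of the same number correlated by -0.043, 0.126 and -0.063, which leaves open that chimera libraries of the same number came from the same recipients.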

Other observations

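WT alveolar macrophages that had regrown from marrow in the chimeras can be set against those of steady-state lungs, a comparison chosen after the data were seen and confounded with the library series. It passed for 5039 genes, 992 higher and 4047 lower in chimera cells, or 2466 and 2194 of 4660 after rescaling. MHC class II genes were higher, 8 of 11 with 0 lower (9 and 0 after rescaling), including H2-Eb1 (2.70 ± 0.42), H2-Ab1 (2.46 ± 0.37) and Cd74 (2.23 ± 0.43). The list had adjusted p = 6.33e-07, and adjusted p = 0.298 with an estimated correlation. Camera also pointed up for lists of interferon-response (adjusted p = 1.55e-05), matrix (1.65e-05) and inflammatory genes (0.00016), chemokines (0.00106), hypoxia and glycolysis (0.00127), mitosis (0.00263), cholesterol synthesis (0.00778), inhibitors of the cell cycle (0.0277), and markers of interstitial macrophages and monocytes (0.00862) and of lung epithelium (0.0276). None of these passed with an estimated correlation. Other genes higher in chimera cells were Lrg1 (3.81 ± 0.23) and S100a6 (3.66 ± 0.24). Lower in chimera cells were Apoc1 (-4.79 ± 0.34), Marco (-4.25 ± 0.22) and Apoe (-2.25 ± 0.15).

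Under both scalings 222 genes were higher and 114 lower in DKO cells of all 3 populations. Chosen after their values were seen, they include, in steady state, chimeras and peritoneum, Trnp1 (5.47, 3.54 and 2.42), the receptor for platelet-activating factor Ptafr (4.38, 3.81 and 2.01), Fcna (5.01, 3.91 and 1.95), Maf (1.46, 1.42 and 1.08) and, lower, S100a4 (-2.45, -1.17 and -1.27).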
